A study of Homo sapiens with 6 samples.

How the data were processed

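RNA was sequenced from 6 libraries of MCF-7 cells, 3 controls and 3 treated with 0.5 mM carboplatin, prepared with the NEBNext Ultra RNA kit per the labels' protocols. This kit does not mark strand, so overlapping sense and antisense genes cannot be told apart, and the strand setting of the counting is not stated. HISAT2 2.0.5 and featureCounts 1.5.0 were used with genome build GRCh38, per the submitters' processing notes. The values were deposited as FPKM, 1 column per library, with the gene length that the authors divided by, per the file headers. The table held 61635 genes with no filter on low values, of which 29974 had a read in any library, and 0 per-sample columns were left unused.

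Multiplying each FPKM value by the gene length gave whole multiples of 1 step per library (tolerance 0.1 read, 100% of the values), from which reads were recovered. The scale that the authors divided by was 1.37 to 1.43 times the total of recovered reads in the controls and 0.667 to 0.702 times after carboplatin, so the deposited FPKM is not scaled to the library total. The implied scales were proportional to median-of-ratios size factors within 1%. Recovered reads ranged from 12109154 to 18710104 per library. A count of 3 reads, the limit that a count of 0 allows, equals 0.121 to 0.122 FPKM for a transcript of 1 kb in the controls and 0.240 to 0.353 FPKM after carboplatin, and covers counting error only. Coordinates are those of the deposited table. Of its genes 58437 matched GENCODE release 29 by identifier, 78.0% of them with identical coordinates. Counting could divide reads between near-identical copies, so ribosomal protein, histone, metallothionein, heat shock and mitochondrial genes are uncertain singly.

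The main test was limma (lmFit and eBayes with a trend) on log2(FPKM + 1) for 13220 genes with a mean FPKM of at least 0.5, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate changes of weakly expressed genes. Gene lists (34, of which 31 had at least 5 measured members) were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with fry as a second test. The lists covered p53 targets, genes lowered through p53, p21 and DREAM, DNA replication, histones, 6 lists of DNA repair and damage signalling, pro- and anti-apoptotic genes, oestrogen receptor targets, luminal and mesenchymal genes, interferon, NF-kB, immediate early, unfolded protein, integrated stress, NRF2, platinum transport, heat shock, cholesterol, hypoxia, respiratory chain, mitochondrial mRNA, ribosomal protein, ribosome biogenesis, senescence and autophagy genes, and markers of leukocytes, fibroblasts, and endothelial cells and adipocytes. The relation with genomic span was a Spearman correlation over 10234 protein-coding genes. Transcript length below is the deposited gene length, which can differ from the length of the transcript expressed.

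Genes named are 9 chosen in advance (CDKN1A, MDM2, TP53, GDF15, ESR1, MKI67, MYC, ERCC1 and SLC31A1), the 10 largest rises and 10 largest falls among protein-coding genes past the test with a mean of at least 1 FPKM and no overlap of the groups, and in each list up to 4 members with the largest changes and up to 2 in the opposite direction. MT-RNR1, MT-RNR2, RN7SL1, RN7SL3 and RNA5-8SN3 fall outside this rule and were chosen after their values were seen.

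The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values or a mean FPKM of at least 2, median-of-ratios size factors, TPM, quantile normalization, protein-coding genes alone, the replicate number as a block, limma without the trend or with a robust prior, an adjusted p under 0.01, camera with an estimated correlation, fry, transcript length in place of span, a partial correlation given mean expression, and each library left out in turn. Added later were limma voom on the recovered reads and FPKM scaled to the total of recovered reads. The span result has no protein-coding alternative because it already uses those genes alone, and camera has no robust-prior counterpart.

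The test was checked on simulated data with 12932 genes. It recovered 100% of 33 genes raised 4-fold and of 32 lowered 4-fold, 67.6% of 34 raised 2-fold and 65.6% of 32 lowered 2-fold, 5.88% of 34 raised 1.5-fold and 21.2% of 33 lowered 1.5-fold, and called 0.110% of 12734 unchanged genes. Over 13220 simulated genes camera called the 1 list that was shifted and 0 unchanged lists, and the correlation with span was 0.0017 where no gene depended on span. Simulated genes were drawn independently, and few of them changed. The check therefore does not cover lists with correlated members or a change of most genes. The spread between simulated libraries was set by hand and not estimated from these data, so the shares recovered need not hold here. R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.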

Results

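The transcriptome of MCF-7 cells, an established oestrogen receptor-positive human breast cancer line, was measured by mRNA sequencing with and without carboplatin, a platinum drug that forms adducts and crosslinks on DNA. The design compared 3 control libraries with 3 libraries from cells exposed to 0.5 mM carboplatin, and the stated purpose was to describe how platinum chemotherapy changes the transcriptome. How long the cells were exposed is not given in the sources used here. The deposited FPKM values resolved into whole reads. These amounted to 18056282, 17117622 and 17368987 reads in control replicates 1, 2 and 3, and to 12109154, 13772744 and 18710104 reads in carboplatin replicates 1, 2 and 3. At least 1 read was recorded for 23844 ± 515 genes (SD, n = 3) in the controls and for 19464 ± 565 genes (SD, n = 3) after carboplatin. Libraries of the same group correlated between 0.986 and 0.993 across genes (Pearson's r of log2 values), and no pair agreed within sampling noise. These correlations cover all 61635 genes, including those without a read in any library, which raise r. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

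Carboplatin changed most of the measured transcriptome. PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 2.02 ± 0.618 to 170 ± 3.54 FPKM (SD, n = 3 per group), and the DNA damage and stress genes GADD45A, ATF3, GDF15 and CDKN1A rose with it. ESR1, which encodes the oestrogen receptor, fell from 10.5 ± 0.519 to 2.44 ± 0.229 FPKM, and GATA3, a transcription factor of luminal breast cells, fell from 145 ± 10.6 to 10.9 ± 1.52 FPKM. Ribosomal protein genes, replication-dependent histone genes and nuclear genes of the respiratory chain were higher as groups, and oestrogen receptor targets and luminal genes were lower. None of these 5 list calls held in camera with an estimated correlation (adjusted p = 0.46, 0.18, 0.18, 0.18 and 0.40 with an estimated correlation). On the deposited scale the median change was positive among genes with a short genomic span and negative among those with a long one.

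Of 13220 genes with a mean of at least 0.5 FPKM, 4998 were raised and 4722 were lowered (limma, adjusted p below 0.05), together 73.5% of those tested. The genes raised at least 2-fold numbered 2232 and the genes lowered at least 2-fold 1701, but the latter numbered 2881 with a pseudocount of 0.1 and 2959 with voom. Under the depth-based scaling and TPM described next these counts were 675 and 480 raised, and 4769 and 7625 lowered. The groups did not overlap for 77.0% of the genes, where chance gives 10%. Directions depend on the scaling: the deposited values follow size factors, which place the median gene near no change (0.04 on the log2 scale). Scaling to the total of recovered reads (the depth-based scaling) shifted the median of all genes by -0.71, and scaling to TPM shifted it by -1.28. The split then became 1982 raised and 8618 lowered genes under the depth-based scaling, and 1117 raised and 10022 lowered genes in TPM. All 4722 lowered genes were also lowered under both of these scalings. In TPM 1117 of the 4998 raised genes stayed raised and 2499 were lowered, so a moderate rise below is a rise relative to the median gene.

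The reads were also distributed differently over RNA classes. The mitochondrial ribosomal RNAs took 1.30 ± 0.0557% of the reads in the controls and 12.6 ± 1.17% after carboplatin (SD, n = 3 per group). Ribosomal protein genes took 10.1 ± 0.582% and 24.2 ± 1.33%. Processed pseudogenes, of which many are copies of ribosomal protein genes, took 1.13 ± 0.0408% and 2.50 ± 0.110%. Protein-coding genes as a whole took 95.8 ± 0.134% and 83.1 ± 1.08%. These shares moved with the treatment and accompany each gene group below.

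**Figure D1:**
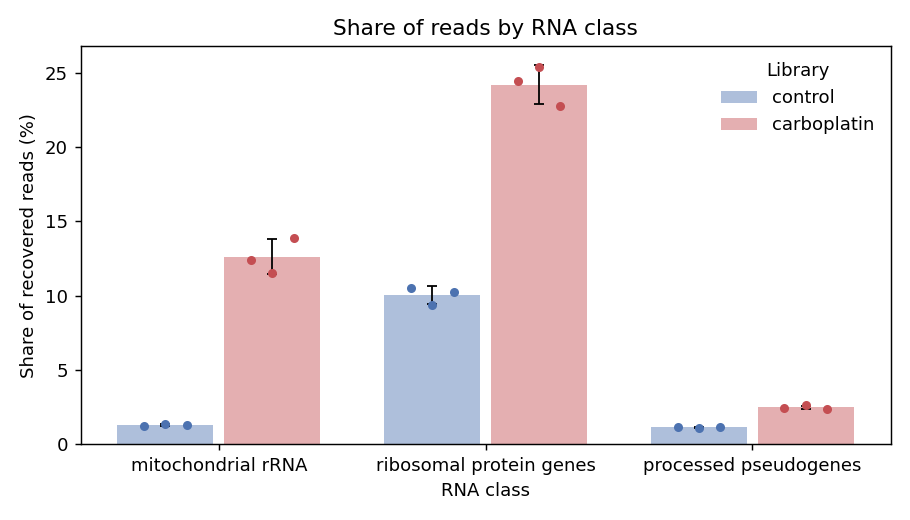
Share of recovered reads (%, linear axis from 0) taken by mitochondrial rRNA, ribosomal protein genes and processed pseudogenes; bars are means of 3 libraries, error bars SD, points single libraries. Mitochondrial rRNA stands at 1.30% in the controls and 12.6% after carboplatin.

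The 10 largest rises among protein-coding genes past the test, with a mean of at least 1 FPKM and groups that did not overlap, were those of PMAIP1, HSPA6, ATF3, H4C3, GADD45A, RGS2, OSGIN1, H3C2, H2AC21 and FOS. PMAIP1 (ENSG00000141682, chromosome 18, 59899996 to 59904305, GRCh38) had a log2 fold change of 5.84 (SE 0.14, limma adjusted p = 4.7e-07), an 83.9-fold rise of the mean FPKM. HSPA6, an inducible HSP70 chaperone, rose 112-fold to a mean of 48.7 FPKM. ATF3, a stress-induced transcription factor, rose 49.3-fold to 43.3 ± 3.93 FPKM. GADD45A, a growth arrest gene induced by DNA damage, rose 18.8-fold to 92.2 ± 10.0 FPKM. FOS, an immediate early transcription factor, rose from 3.60 ± 0.737 to 50.5 ± 3.44 FPKM, and OSGIN1, an oxidative stress-induced growth inhibitor, rose 15.8-fold. RGS2, a regulator of G-protein signalling, rose from 0.220 ± 0.0674 to 16.2 ± 1.28 FPKM. All 10 were also raised under the depth-based scaling, TPM and quantile normalization.

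The 10 largest falls under the same rule were those of IGFBP5, DKK1, GATA3, EDN1, IRX3, INHBB, RTN4RL1, TNRC18, GRHL2 and ZHX2. IGFBP5, a binding protein for insulin-like growth factors, fell 28.7-fold, from 50.9 ± 10.6 to 1.77 ± 0.347 FPKM. DKK1, a secreted Wnt antagonist, fell 26.7-fold, and EDN1, the endothelin-1 gene, fell 21.5-fold. GATA3 (ENSG00000107485, chromosome 10, 8045378 to 8075198, GRCh38) had a log2 fold change of -3.61 (SE 0.11, limma adjusted p = 5.2e-07). GRHL2, an epithelial transcription factor, fell 13.4-fold, and INHBB, an inhibin and activin subunit, fell 12.2-fold. IRX3, a homeobox gene, fell 11.6-fold. RTN4RL1, TNRC18 and ZHX2 fell by 3.13, 3.12 and 3.08 on the log2 scale. These 10 were lowered under every scaling tried.

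**Figure D2:**
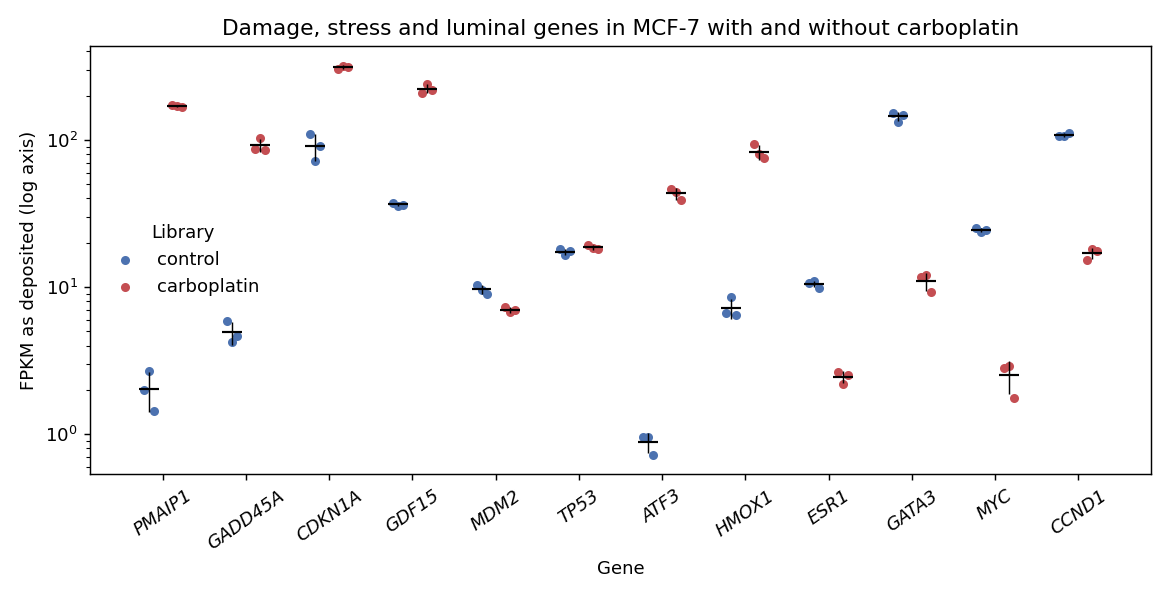
FPKM as deposited (log axis) of 12 genes in each library; points are libraries, horizontal bars means and vertical bars SD of 3 libraries. PMAIP1 stands at 2.02 FPKM in the controls and 170 FPKM after carboplatin, and GATA3 at 145 and 10.9 FPKM; of these 12 genes TP53 did not pass the test (its direction turned under the depth-based scaling, TPM and quantile normalization).

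The p53 target list, fixed before the data were examined, split. Of its 42 measured members 22 rose, 11 fell and 9 did not pass. PMAIP1, GADD45A, SERTAD1 (log2 3.19) and TRIAP1 (log2 2.96) rose most. CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687337), rose from a mean of 90.6 FPKM to 313 ± 8.36 FPKM (log2 1.80, SE 0.14, limma adjusted p = 2.2e-05); in TPM its change was 0.29 (adjusted p = 0.060, with a range of 5.2e-10 to 0.060 over its alternatives). GDF15, a stress-induced cytokine, rose 6.12-fold to 223 ± 15.5 FPKM. MDM2, the p53 ubiquitin ligase and itself a p53 target, fell from 9.65 ± 0.680 to 7.02 ± 0.315 FPKM (log2 -0.41, limma adjusted p = 0.0016). The largest falls in the list were those of SUSD6 (log2 -1.97) and KITLG (log2 -1.77). TP53 itself stood at 17.4 ± 0.842 and 18.7 ± 0.692 FPKM (limma adjusted p = 0.19). As a list the p53 targets were not called (median 0.36, camera adjusted p = 0.11; 0.88 with an estimated correlation, the adjusted p ranging from 0.0020 to 0.88 over the alternatives). The list passed with no filter on low values, with protein-coding genes alone, under the depth-based scaling and in TPM; under the latter 2 scalings its median was negative (-0.39 and -0.89) but 0.28 and 0.35 above that of all genes.

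Genes of cell death moved in both directions, although in TPM 19 of the pro-apoptotic and 6 of the anti-apoptotic genes were lowered. Of 24 measured pro-apoptotic and death receptor genes 9 rose, 9 fell and 6 did not pass (camera adjusted p = 0.91). Besides PMAIP1, CYCS, which encodes cytochrome c, rose (log2 2.22). FADD, the adaptor of death receptors, fell (log2 -1.99), as did APAF1, the scaffold of the apoptosome (log2 -1.38). Of 8 anti-apoptotic genes 3 rose and 5 fell (camera adjusted p = 0.53). BCL2L1, which encodes BCL-XL, fell from 15.8 ± 0.821 to 3.90 ± 0.239 FPKM, and XIAP, a caspase inhibitor, from 9.40 ± 0.650 to 2.71 ± 0.293 FPKM. BIRC5, the survivin gene, rose (log2 1.46), although in TPM its change was -0.01. MCL1 rose (log2 0.44), which turned to -0.69, -0.58 and -1.07 under quantile normalization, the depth-based scaling and TPM.

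Cell cycle genes did not move as a block. In the list of genes that p53 lowers through p21 and the DREAM complex, 24 of 38 measured members rose, 8 fell and 6 did not pass. PTTG1, the securin gene, rose from 27.3 ± 3.21 to 203 ± 5.87 FPKM, and CDK1, the mitotic kinase, rose as well (log2 1.60); in TPM CDK1 did not pass (log2 0.12). MKI67, the Ki-67 proliferation marker, fell from 15.2 ± 1.03 to 5.63 ± 1.32 FPKM. FOXM1, a transcription factor of mitotic genes, fell (log2 -1.65), as did MELK (log2 -0.92). The list was called as higher (median 0.66, camera adjusted p = 0.033; adjusted p = 0.88 with an estimated correlation). The call was lost under the depth-based scaling and in TPM (adjusted p = 0.19 and 0.85; 0.00018 to 0.88 over the alternatives), where its median was -0.28 and -0.75, or 0.39 and 0.49 above that of all genes. The call also ended with a mean FPKM filter of 2, under quantile normalization and without carboplatin replicate 3 (adjusted p = 0.076; 0.00018 to 0.88 over the alternatives). The DNA replication list was not called (18 of 40 members raised, 10 lowered, camera adjusted p = 0.51). ORC6, an origin recognition subunit, rose (log2 1.70) and MCM3, a helicase subunit, fell (log2 -0.90). With no filter on low values this list was called as higher, and in TPM as lower (median -1.38, or -0.14 relative to all genes; adjusted p = 0.044 and 0.045, with a range of 0.044 to 0.88 over the alternatives).

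Replication-dependent histone genes rose together: 43 of 44 measured members were raised, with a median log2 fold change of 1.79 (camera adjusted p = 7.0e-10; adjusted p = 0.18 with an estimated correlation). H4C3 rose from 0.534 ± 0.250 to 31.6 ± 4.44 FPKM and H3C2 from 0.873 ± 0.207 to 21.3 ± 1.54 FPKM. H4C1 (log2 3.18), H3C7 (log2 3.06) and H2AC21 (log2 3.55) rose as well. Some members passed the filter on low values only through carboplatin: the control mean was 0.438 FPKM for H4C1 and 0.273 FPKM for H2AC21. The count of raised members is partly set by this, and how many passed in this way was not counted. With no filter on low values no list called in the main test lost its call. The list's median stayed above 0 under every scaling, at 1.79, 1.09 and 0.91 under quantile normalization, the depth-based scaling and TPM. Most mRNAs of these genes lack a poly(A) tail, and near-identical copies make the value of a single histone gene uncertain.

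Genes of the cytosolic ribosome showed the largest median shift of the lists on the deposited scale and under the depth-based scaling relative to all genes, but not under quantile normalization or in TPM, where histone genes shifted more. Of 73 measured ribosomal protein genes 71 rose, none fell and 2 did not pass, with a median log2 fold change of 2.38 (camera adjusted p = 1.8e-21; adjusted p = 0.46 with an estimated correlation). RPS29 rose from 40.1 ± 4.50 to 419 ± 97.2 FPKM, RPL39 from 231 ± 8.83 to 1916 ± 208 FPKM, and RPS27 from 983 ± 48.8 to 7626 ± 1084 FPKM. The RPS29 interval contains that of RN7SL1, and the kit does not mark strand. Whether the RPS29 value includes RN7SL1 reads was not tested. The median was 0.64, 1.34 and 0.86 under quantile normalization, the depth-based scaling and TPM. Reads shared with processed pseudogenes leave single ribosomal protein values uncertain, and 373 of 588 measured processed pseudogenes were raised. Ribosome biogenesis factors were not called as a list (20 raised, 13 lowered of 39, or 21 and 14 adjusted over the list alone; camera adjusted p = 0.53). NOP10, a small nucleolar ribonucleoprotein subunit, rose (log2 2.37), and POLR1A, the largest subunit of RNA polymerase I, fell (log2 -1.81).

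Nuclear genes of the respiratory chain rose in the same way, 52 of 53 measured members (median log2 1.79, camera adjusted p = 1.6e-15; adjusted p = 0.18 with an estimated correlation). COX6A1 rose 6.74-fold and COX6C 6.43-fold, both subunits of cytochrome c oxidase, and NDUFA4 rose 6.72-fold. The median stayed above 0 under quantile normalization (0.75), the depth-based scaling (0.77) and TPM (0.32). This list was not compared with random lists matched on genomic span. The 13 mRNAs encoded by the mitochondrial genome had a median of 0.07, with 3 raised and 4 lowered (camera adjusted p = 0.91). Their mean was -0.07, and their median against the control mean was -0.23, -0.15 and 0.39 in carboplatin replicates 1, 2 and 3, so the sign of the median rests on replicate 3. MT-ND6 fell from 1317 ± 200 to 499 ± 40.3 FPKM. MT-CO2 rose from 8825 ± 493 to 16525 ± 4306 FPKM, a change that turned to -1.56, -0.16 and -0.65 under quantile normalization, the depth-based scaling and TPM, and that did not pass with no filter on low values. Under quantile normalization the mitochondrial mRNAs were called as lower (median -1.68, adjusted p = 1.6e-05; 1.6e-05 to 0.99 over the alternatives). That scaling gives every library the same set of values, so the most abundant RNAs can only trade places. MT-CO2 (-1.56) and MT-RNR2 (1.56) mirrored each other there, and the call does not by itself show a fall of mitochondrial mRNAs. The mitochondrial ribosomal RNAs, chosen after their values were seen, were 16.1-fold higher for MT-RNR2 and 48.3-fold higher for MT-RNR1.

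**Figure D3:**
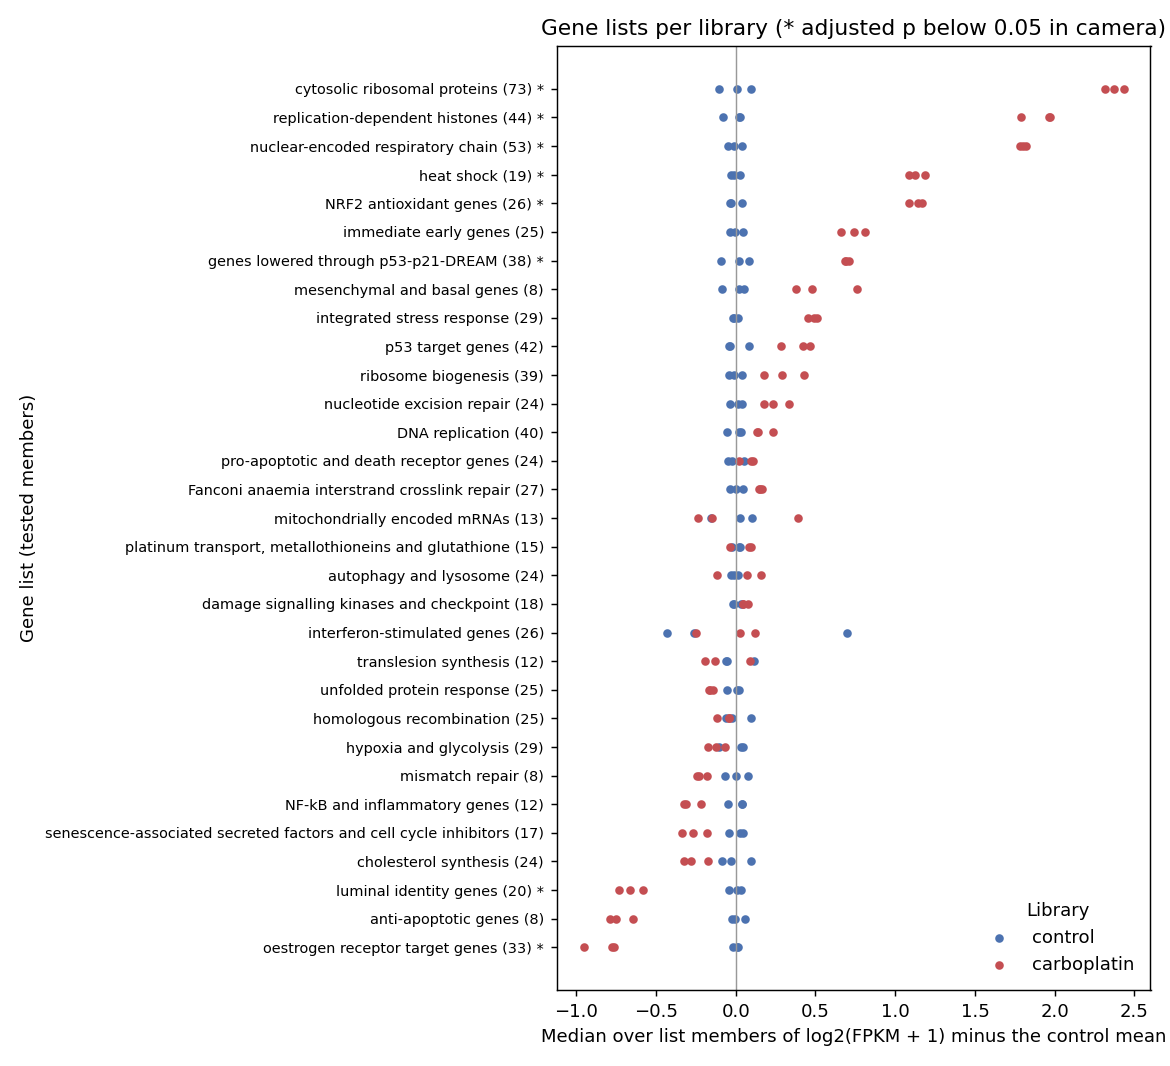
Median over the tested members of each gene list of log2(FPKM + 1) minus the control mean, per library, as deposited. Asterisks mark the 8 lists called in camera at the preset correlation, of which 0 were called with an estimated correlation; the carboplatin libraries lie between 2.31 and 2.43 for ribosomal proteins and between -0.95 and -0.76 for oestrogen receptor targets, and the median of the heat shock list turns below 0 under quantile normalization and in TPM.

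Heat shock genes rose, 17 of 19 measured members, with 1 lowered (median log2 1.13, camera adjusted p = 5.4e-05; adjusted p = 0.18 with an estimated correlation). Besides HSPA6, DNAJB4, an HSP40 co-chaperone, rose 9.40-fold and HSPE1, the mitochondrial HSP10 gene, 4.57-fold. HSPA4 fell (log2 -0.31), which did not pass without control replicate 2 or with no filter on low values (adjusted p = 0.071 and 0.051; 1.0e-06 to 0.071 over its alternatives). The list's median was -0.18 under quantile normalization and -0.34 in TPM, where the call ended, and lay 0.91 above that of all genes in TPM.

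Targets of NRF2, the transcription factor of the antioxidant response, rose in 20 of 26 measured cases and fell in 2 (median log2 1.13, camera adjusted p = 5.4e-05; adjusted p = 0.40 with an estimated correlation). HMOX1, heme oxygenase 1, rose from 7.21 ± 1.13 to 83.0 ± 9.50 FPKM. GPX2, a glutathione peroxidase, rose 25.1-fold, and FTL, the ferritin light chain gene, 7.10-fold to 3019 ± 39.9 FPKM. GSR, glutathione reductase, fell (log2 -0.29), and ABCC1 fell more, from 1.10 ± 0.209 to 0.0169 ± 0.00376 FPKM (log2 -1.04). The carboplatin values of ABCC1 lie below the limit of 3 reads for its 7575 bases, so its level and SD there are uncertain. The list was not called under quantile normalization (median 0.37), and in TPM its median was -0.23, or 1.01 above that of all genes. The list of platinum transport, metallothionein and glutathione genes was not called (6 raised, 7 lowered of 15, camera adjusted p = 0.93). MT2A, a metallothionein with close paralogs, rose 11.4-fold, and ATOX1, a copper chaperone, 3.48-fold. SLC31A1, the copper transporter CTR1, fell from 12.6 ± 0.760 to 9.83 ± 1.53 FPKM (limma adjusted p = 0.026). That call was lost without control replicate 1, control replicate 2, carboplatin replicate 1 or carboplatin replicate 2 (adjusted p = 0.076, 0.082, 0.056 and 0.056), and with no filter on low values (adjusted p = 0.065; 1.9e-06 to 0.082 over its alternatives).

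Other stress responses were mixed within their lists, although in TPM 20 of the integrated stress response, 22 of the unfolded protein response and 14 of the immediate early genes were lowered. Of 29 integrated stress response genes 16 rose and 9 fell (camera adjusted p = 0.31); the list was called with no filter on low values (adjusted p = 0.0497; 0.0497 to 0.99 over the alternatives). DDIT3, the CHOP gene, rose from 4.61 ± 0.363 to 47.4 ± 3.03 FPKM, while the amino acid transporters SLC7A5 and SLC38A2 fell 4.68-fold and 5.86-fold. Of 25 unfolded protein response genes 8 rose and 12 fell (camera adjusted p = 0.53). SEC61B, a subunit of the translocon, rose (log2 1.74) and SEL1L, of endoplasmic reticulum-associated degradation, fell (log2 -1.59). Of 25 immediate early genes 14 rose and 7 fell (camera adjusted p = 0.25). FOSL1 rose (log2 2.35), whereas JUND fell (log2 -1.42). The immediate early list was called with no filter on low values, under the depth-based scaling and in TPM (adjusted p = 0.014, 0.034 and 0.041; 0.014 to 0.88 over the alternatives), where its median was negative under the latter scalings (-0.13 and -0.60) but 0.54 and 0.64 above that of all genes.

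Oestrogen receptor targets fell in 22 of 33 measured cases and rose in 8, or fell in 23 adjusted over the list alone (median log2 -0.77, camera adjusted p = 0.0024; adjusted p = 0.18 with an estimated correlation). MYC fell from 24.4 ± 0.809 to 2.50 ± 0.640 FPKM, GREB1, a receptor cofactor, from 15.9 ± 0.366 to 1.39 ± 0.0673 FPKM, and CCND1, the cyclin D1 gene, from 108 ± 3.34 FPKM to a mean of 17.1 FPKM. RARA, a retinoic acid receptor, fell 10.5-fold. TFF1, a secreted trefoil peptide, went the other way, from 986 ± 84.6 to 2273 ± 147 FPKM. Its change turned to -0.53 under quantile normalization and -0.32 in TPM, and that of AGR2 (log2 1.05) turned to -0.09 in TPM; neither passed under the depth-based scaling.

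Luminal identity genes fell in 14 of 20 cases and rose in 1 (median log2 -0.64, camera adjusted p = 0.0013; adjusted p = 0.40 with an estimated correlation). ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619) fell 4.29-fold (log2 -1.74, SE 0.08, limma adjusted p = 1.7e-06). CDH1, which encodes E-cadherin, fell (log2 -1.86), and PRLR, the prolactin receptor gene, fell from 8.73 ± 1.83 to 2.25 ± 0.112 FPKM. EPCAM rose (log2 0.53), which turned to -0.67, -0.50 and -0.98 under quantile normalization, the depth-based scaling and TPM. The medians of both lists were negative under every scaling and at least 0.68 below that of all genes. Of 8 measured mesenchymal and basal genes 4 rose and 2 fell (camera adjusted p = 0.68). SNAI1, a repressor of E-cadherin, rose from 0.262 ± 0.0952 to 8.70 ± 1.44 FPKM, and TGFB1 fell (log2 -0.89).

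DNA repair lists were not called as lists, and their members went both ways; in TPM most members of each were lowered. Nucleotide excision repair, which removes platinum adducts, had 12 raised and 6 lowered genes of 24 (camera adjusted p = 0.31). RPA3, a subunit of the single-strand binding protein, rose (log2 2.08), as did CETN2 (log2 1.74; 0.27 and not past the threshold in TPM), and RAD23A fell (log2 -0.63). ERCC1, the subunit of the incision nuclease, rose from 4.52 ± 0.153 to 6.22 ± 0.617 FPKM (limma adjusted p = 0.0042), a change that turned to -0.49 under the depth-based scaling and -0.99 in TPM. Crosslink repair by the Fanconi anaemia pathway had 11 raised and 7 lowered genes of 27, with 10 raised adjusted over the list alone (camera adjusted p = 0.54). CENPS rose (log2 1.60), while FAAP100 (log2 -1.45) and BRIP1 (log2 -0.92) fell. Homologous recombination had 10 raised and 9 lowered genes of 25 (camera adjusted p = 0.93), with a median of -0.11 and a mean of 0.0053. XRCC2 fell (log2 -1.32), and RAD51C rose (log2 1.04) but stood at 0.01 and 0.02 under quantile normalization and the depth-based scaling and at -0.46 in TPM.

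Mismatch repair had 1 raised and 4 lowered genes of 8 (camera adjusted p = 0.53), among them PMS2 (log2 -1.28) and MSH3 (log2 -0.83). Translesion synthesis had 4 raised and 4 lowered genes of 12 (camera adjusted p = 0.93; median -0.10, mean 0.0090), with MAD2L2 raised (log2 1.58) and HLTF lowered (log2 -1.47). Damage signalling and checkpoint genes had 8 raised and 6 lowered of 18 (camera adjusted p = 0.91). WEE1, the checkpoint kinase, fell (log2 -0.93). H2AX rose (log2 0.97), which turned to -0.39, -0.06 and -0.54 under quantile normalization, the depth-based scaling and TPM.

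Among 31 lists with at least 5 measured members, 8 were called, 6 as higher and 2 as lower. None was called by camera with a correlation estimated per list, where 4 had an unadjusted p below 0.05. The estimated correlation was 0.52 for ribosomal protein genes, but 0.02 for heat shock genes and -0.02 for oestrogen receptor targets, which also lost their calls. The preset was 0.01. A higher correlation thus does not account for the lost call of oestrogen receptor targets, and hardly for that of heat shock genes. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries, which lowers its power. A call lost there therefore does not show that correlation among members had made it. What else removed the calls was not tested. The second test, fry, asks whether a list's genes move on balance one way, and called 26. Counts adjusted over the list alone equalled those over all genes in the lists above unless given. Only the ribosomal protein list was compared with random lists matched on genomic span. For the other lists, raised or lowered, a change of the pathway cannot be told apart from the relation with span described next.

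The change depended on the length of the gene in the genome. Platinum adducts can stop RNA polymerase, so a relation with genomic span was a question set in advance. Across 10234 protein-coding genes the log2 fold change correlated negatively with span (Spearman's rho = -0.46; genes are not independent replicates). The genes were ranked by span and parted into 5 groups of equal size. In the group with the shortest spans, up to 10.1 kb, 60.4% were raised and 20.2% lowered, and the median change was 0.61. In the next groups, up to 22.2 and 42.4 kb, the median was 0.30 and 0.07, and in the last 2 groups -0.24 and -0.71. In the group with the longest spans, with a median span of 139 kb, 10.1% were raised and 74.8% lowered. The rho of each carboplatin library against the control mean was -0.46, -0.47 and -0.45.

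The order of the span groups was the same under every scaling, although the sign of a group was not. The shortest group had a median of -0.24 under the depth-based scaling and -0.71 in TPM, and the longest -1.35 and -2.11. Under quantile normalization the middle group stood at -0.02. Rank correlations do not weigh the size of a change: 5 of the 10 splits of the 6 libraries gave a rho at least as far from 0 (exact permutation test, 2-sided, p = 0.5). The difference of medians between the shortest and the longest group, a measure added after the result was seen, was 1.32 for the real groups and at most 0.49 for the other splits (exact permutation test, 2-sided, p = 0.1, the smallest p that 3 against 3 libraries allow). Transcript length gave nearly the same rho (-0.45) and correlated with span (rho = 0.62).

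**Figure D4:**
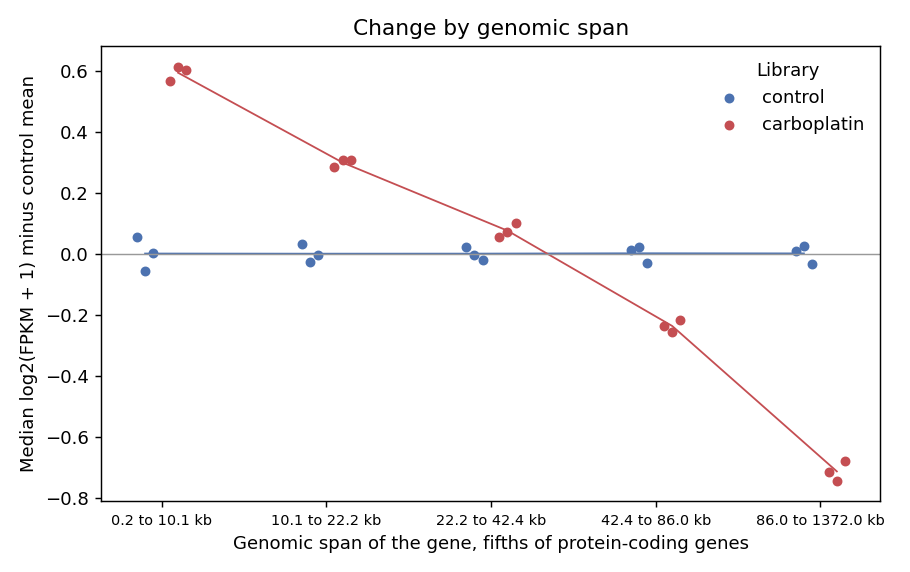
Median of log2(FPKM + 1) minus the control mean, as deposited, for 5 equal groups of 10234 protein-coding genes by genomic span (kb); points are libraries and lines the group means. The carboplatin medians run from 0.61 in the shortest to -0.71 in the longest group; under the depth-based scaling and in TPM all 5 groups lie below 0 in the same order.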

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

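The alternatives voom on recovered reads and FPKM scaled to the total of recovered reads (the depth-based scaling) were chosen after seeing the data. Of 115 named genes, 112 kept direction and side of the threshold under all alternatives other than the depth-based scaling, TPM and quantile normalization. The exceptions were SLC31A1, HSPA4 and MT-CO2. ABCC1 is not among the 115 and was not followed through the alternatives. Over named genes and alternatives 2138 values were the same in this sense, 18 lost the call and 23 reversed, and over single lists 556 were the same, 15 lost a call, 15 gained a call and 2 reversed, where the direction of a list is camera's, relative to other genes. The median of a list itself changed sign for 17 of 31 lists in TPM, 14 under the depth-based scaling and 9 under quantile normalization.

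In TPM 1117 genes were raised and 10022 lowered, and under the depth-based scaling 1982 and 8618, against 4998 and 4722 in the main test. The genes raised at least 2-fold numbered 480 and 675 under these scalings, against 2232, and the genes lowered at least 2-fold 7625 and 4769, against 1701. These scalings shift the median gene by -1.28 and -0.71, which moves the split by construction. In TPM the log2 fold change reversed to -1.39 for TP53, -0.99 for ERCC1, -0.32 for TFF1, -0.086 for AGR2, -0.98 for EPCAM, -0.011 for BIRC5, -1.07 for MCL1, -0.46 for RAD51C, -0.54 for H2AX and -0.65 for MT-CO2, and the DNA replication list to -1.38 (-0.14 relative to all genes). Under the depth-based scaling it reversed to -0.89 for TP53, -0.49 for ERCC1, -0.50 for EPCAM, -0.58 for MCL1, -0.063 for H2AX and -0.16 for MT-CO2. Under quantile normalization it reversed to -0.36 for TP53, -0.53 for TFF1, -0.67 for EPCAM, -0.69 for MCL1, -0.39 for H2AX, -0.35 for GAPDH and -1.56 for MT-CO2, and the heat shock list to -0.18. For MT-CO2 the reversal mirrored the rise of MT-RNR2 (1.56), as this scaling gives every library the same set of values. For the others the cause was not tested.

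The genes lowered at least 2-fold numbered 2881 with a pseudocount of 0.1 and 2959 with voom (the cause was not tested), and 2950 genes were lowered with a mean FPKM of at least 2, where 8547 were tested. Lists called numbered 0 in camera with an estimated correlation (4 at an unadjusted p under 0.05) and 26 in fry, against 8. The rho with span was -0.38 with no filter, -0.45 in TPM, -0.36 under quantile normalization, -0.43 under the depth-based scaling, -0.45 for transcript length and -0.38 as a partial correlation given mean expression, against -0.46; the cause was not tested.

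Leaving out each library in turn gave 8898 to 9582 changed genes, 4541 to 4920 raised, 4301 to 4662 lowered, 2179 to 2303 raised and 1682 to 1746 lowered at least 2-fold, 7 to 8 lists, and a rho of -0.47 to -0.45. SLC31A1 lost its call without control replicate 1, control replicate 2, carboplatin replicate 1 or carboplatin replicate 2, HSPA4 without control replicate 2, and the list lowered through DREAM without carboplatin replicate 3. With no filter on low values SLC31A1, HSPA4 and MT-CO2 lost their calls. With the replicate number as a block 9333 genes (4825 raised and 4508 lowered) and 8 lists were called, and rho was -0.46; the block changed no call of a named gene or list. The correlations between same-numbered libraries were -0.06, -0.07 and -0.04, so the pairing is not borne out, and no library correlated best with its own number. Depth limits weak genes most after carboplatin, where 3 reads equal 0.240 to 0.353 FPKM per kb.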

Other observations

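The 3 tests of RNAs that lack a long poly(A) tail, the count of them with no filter, and the test of scaling for ribosomal protein genes were chosen after the results were seen. Lists on inflammation and metabolism were not called in the main test. Of 26 interferon-stimulated genes 4 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.93). In TPM the list was called as higher relative to other genes, with a median of -0.87 that lay 0.37 above that of all genes (adjusted p = 0.045; 0.045 to 0.997 over the alternatives). B2M rose from 9.18 ± 2.91 to 53.8 ± 3.31 FPKM (SD, n = 3 per group) and STAT2 fell (log2 -0.74). The list's median in control replicate 2 lay 0.70 above the control mean, while controls 1 and 3 lay at -0.26 and -0.43. Of 12 NF-kB genes 2 rose and 5 fell (camera adjusted p = 0.31), with NFKBIA down from 43.1 ± 1.41 to 9.57 ± 2.48 FPKM. Of 17 senescence-associated genes 5 rose and 7 fell (camera adjusted p = 0.54), with VEGFA down (log2 -1.24). Of 24 autophagy and lysosome genes 12 rose and 11 fell, with a median of 0.04 and a mean of -0.03 (camera adjusted p = 0.93). MAP1LC3B rose (log2 1.64; 0.19 in TPM, where it did not pass) and DRAM1 fell (log2 -1.61).

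Of 24 cholesterol synthesis genes 6 rose and 12 fell, or 6 and 13 adjusted over the list alone (camera adjusted p = 0.31). LDLR fell 10.5-fold and SQLE fell (log2 -1.65), while EBP rose (log2 1.43; 0.00 in TPM). The list was called as lower under quantile normalization, the depth-based scaling and TPM (adjusted p = 0.0048, 0.023 and 0.034; 0.0048 to 0.88 over the alternatives). Of 29 hypoxia and glycolysis genes 11 rose and 12 fell (camera adjusted p = 0.55); the list was called as lower under quantile normalization (adjusted p = 0.0048; 0.0048 to 0.97 over the alternatives). HK2 fell 7.45-fold and SLC2A1 5.07-fold, while GAPDH rose (log2 1.55), which turned to -0.35 under quantile normalization and stood at 0.03 in TPM. Among markers of other cells, 1 of 3 measured leukocyte genes rose, 1 of 2 measured fibroblast genes fell, and 0 of the endothelial and adipocyte genes were measured. Of 816 genes in transcription factor families 24.6% were raised and 47.2% lowered (median -0.24), against 3652 raised and 3766 lowered of 9418 other protein-coding genes (median -0.03). The medians were 0.01 against 0.64 among the shortest genes and -0.87 against -0.70 among the longest, and the bZIP family went the other way (51.2% raised). These differences were not tested.

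The fold change fell with genomic span. Transcript length as deposited and GC content do not account for this alone. The partial correlation with span was -0.25 given transcript length and -0.54 given GC content, each in the carboplatin library where it was weakest. The length of the transcript expressed was not tested. Transcript length given span had a partial correlation nearly as strong (-0.23 over all libraries), so both lengths carry a relation of their own. Given transcript length, GC content and mean expression together it was -0.33, which is consistent with polymerase being stopped along the gene body; the relation with transcript length stays open. Differences in RNA half-life between long and short genes were not tested and stay open.

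Several RNAs that lack a long poly(A) tail were higher after carboplatin, but not all of them: MT-RNR1 rose from 1185 ± 7.41 to 57234 ± 6881 FPKM, RN7SL1 from 323 ± 66.2 to 3570 ± 1241 FPKM, RN7SL3 9.78-fold and RNA5-8SN3 from 1.59 ± 1.06 to 153 ± 34.0 FPKM. Of 41 listed structured RNAs 24 were found among the deposited genes, and 11 passed the filter on low values. Of these 11, 9 (81.8%) were higher in every carboplatin library than in every control, but most passed through their carboplatin values. With no filter 9 of 14 with a read were higher and 0 lower. Whether more RNA without a tail was carried into the carboplatin libraries cannot be told apart from other sources. Of 87 snoRNA genes 24 were raised and 2 lowered (median log2 0.60), and of 66 snRNA genes 17 were raised and 9 lowered (median 0.58). Of 94 miRNA genes 13 were raised and 19 lowered, though their median was 0.34. A read equals more FPKM after carboplatin than in the controls. Short genes with few reads can thus pass the filter through carboplatin alone, which favours a positive median. RNU4-1, an snRNA gene, had a log2 of 0.56 with groups that overlapped (limma adjusted p = 0.29). How many genes of these classes rest on few reads was not counted. Of 17 mitochondrial tRNAs 0 were raised and 12 lowered (median -2.32). More mitochondrial RNA of every kind is argued against, since the median of the mitochondrial mRNAs minus MT-RNR2 was -3.92 on the log2 scale. More cells in S phase, which might raise histone mRNA, cannot be told apart from this, because the DNA replication list had a median of 0.12 with members going both ways, and whether poly(A) selection was used is not stated.

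Ribosomal protein mRNAs were higher. Short genomic spans alone do not account for it. The list's median lay 1.28 above that of 10000 random lists matched on span, deposited gene length and expression. None of these lists reached 2.38, although matching on expression was imperfect (median 789 against 125 FPKM). The deposited length had a median of 2930 bases in the list and was 9840 for RPS29, so short transcripts were not matched and stay open. No scaling tried brought the median to 0, and the lowest was 0.64, under quantile normalization. All these scalings are relative within a library. A rise per cell therefore cannot be told apart from a fall of most other mRNAs. A response of these mRNAs to carboplatin may be involved, and a difference in RNA stability was not tested.

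Of the 10 splits of the 6 libraries, 1, the real one, gave 9720 changed genes, and the highest of the other splits gave 0 with limma at the adjusted threshold (48 to 96 at an unadjusted p under 0.05). For lists 5 of 10 splits gave as many, the real split 8 and the highest other 8. The splits are too few for a share under 0.05.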
